A study of Rattus norvegicus with 22 samples.

How the data were processed

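Livers of 22 female Crl:CD(SD) rats, 12 given vehicle and 10 given GSK932121A, were each hybridised to 1 Affymetrix array, per the labels. The rats were 12 weeks old, the dose volume was 10 mL/kg, and biotin-labelled material was made from the median lobe with a whole-transcript kit. The deposited values are on the log2 scale and come from RMA, which corrects the background, normalises between arrays and summarises the probes of each probe set, per the submitters' processing notes. The software that ran RMA, its version and the probe set definition are not given in the sources used here, and the base of the logarithm is that which RMA uses. Values ran from 0.67 to 13.8. Normalising between arrays removes any shift common to all genes, so a change in the total RNA of a liver cannot be seen, and small changes of dim probe sets are compressed towards the background. The number of arrays, not a count of molecules, limits the precision.

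Each array was assigned to its group and replicate number from the labels. The labels give no batch, litter or date. The groups share no replicate numbers, so samples were not paired. Of 36685 probe sets, 18511 had 1 gene symbol in the platform annotation, 575 had several and 17599 had none. Symbols were checked through their Entrez identifiers, of which 18394 matched the gene table used, and 0 symbols changed. Probe sets with several symbols or none were not used in the comparisons of genes. Where a gene had more than 1 probe set (291 genes), the one with the highest mean over all arrays stood for it, which left 18166 genes.

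Genes were compared in limma (version 3.58.1, R 4.3.3) with a fit of group alone, moderated by empirical Bayes with neither an intensity trend nor robust settings. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene passed at an adjusted p under 0.05. Fold changes are 2 to the power of the log2 difference between group means, and "above the highest vehicle array" counts treated arrays beyond the range of the vehicle group. A total of 45 gene lists for pathways and cell types was fixed from textbook knowledge, and 43 with at least 5 measured members were tested with camera, with an inter-gene correlation preset at 0.01 and adjustment over these lists. Camera with an estimated correlation, camera on ranks and fry stood beside it. Of 697 measured members, 20 belong to more than 1 pathway list.

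The spread between animals was compared by the median over genes of the log2 ratio of SDs, and the first principal component by the difference of group means, each with a two-sided permutation test of 100000 resamples (10000 for the alternatives of the spread and 1000 for the median absolute deviation). These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots used matplotlib 3.10.9. The groups, the tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined.

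That rule named the 15 largest rises and the 15 largest falls among genes that passed, leaving out unnamed loci, microRNAs and the like, all complex III genes, the 4 members of each other list with the largest difference, the largest opposite change that passed, and a short set of genes that included Fgf21, Gdf15 and Alb. List members so named that did not pass are given as counts, apart from those of complex III. Some genes outside the rule were added after their values were seen, so that each short count of calls names its members: Cth, Eif4ebp1, Otc, Sesn1, Cxcl11, Polg2, P4ha1, Creb3l3, Acsl1, Gpam, Fads1, Dnajb1, Slc30a10, Phlda3, Akr1b7, Usp2 and, for a test in the closing section, Cyp2c12.

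The alternatives were median centring, renewed quantile normalisation and cyclic loess normalisation of the deposited values, filters at a mean log2 value of 5 or 7, the mean of a gene's probe sets, an intensity trend with robust settings, array weights, the Welch and Wilcoxon rank sum tests, all probe sets, a test against a 1.2-fold change, other set tests, another measure of spread, scaled genes before the principal components, and each array left out in turn. Lists without the members that another list holds, and surrogate variables from limma's wsva, were added after the data were seen. The latter took the place of the planned sva package, which was not used here, and their number, 5, came from components of the residuals that exceeded those of permuted residuals. The limma fit was tested on simulated data for the 18166 genes: of genes changed 1.2-fold, 1.5-fold and 2-fold it recovered 34.8% of 66, 82.1% of 67 and 100% of 67, with 10 unchanged genes called. The simulation drew genes independently from normal distributions, with the same SD in both groups and 200 changed genes. The real genes are correlated, some SDs differ between groups and more genes passed, so these rates need not hold for the real comparison. Plasma exposure and body temperature of single animals were not used here.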

Results

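Liver expression was measured on 22 Affymetrix whole-transcript arrays, each hybridised with RNA from the median lobe of 1 female Crl:CD(SD) rat, an outbred Sprague-Dawley stock. Of these rats, 12 received vehicle and 10 received GSK932121A, named in the series title as an inhibitor of mitochondrial complex III, the cytochrome bc1 complex that passes electrons from ubiquinol to cytochrome c. The compound was given as a single intraperitoneal dose of 50 mg/kg, and the livers of this group were taken after 5 hours. The labels give no time for the vehicle group. The study dosed 12 rats per group, and its submitters left out 2 treated animals in which little compound had reached the plasma. Array medians lay between 4.73 and 4.85 on the log2 scale, and the correlation between any pair of arrays, taken across genes, which are not independent replicates, lay between 0.971 and 0.991. No pair of arrays held identical values. The number of arrays limits the precision of every value given here.

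The main comparison asked which liver genes differ between GSK932121A and vehicle. Among genes kept by the naming rule, the largest rise was that of Coq10b, which encodes a coenzyme Q-binding protein of the inner mitochondrial membrane. Its log2 value was 10.77 ± 0.97 after GSK932121A and 6.90 ± 0.51 after vehicle (SD, n = 10 and 12), a 14.7-fold difference (limma, adjusted p = 2.15e-09). Chac1, a glutathione-degrading enzyme, rose 12.7-fold, and Gadd45b, a growth arrest and DNA damage response gene, rose 11.9-fold. Ppargc1a, the transcriptional coactivator PGC-1alpha, rose 8.18-fold, from 6.25 ± 0.47 to 9.28 ± 1.14 (SD, n = 12 and 10; adjusted p = 3.9e-07). Slc38a2, a neutral amino acid transporter, rose 7.51-fold, from 9.00 ± 0.51 to 11.91 ± 0.35, with the smallest adjusted p among the named genes, 3.39e-11.

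All 10 treated arrays lay above the highest of the 12 vehicle arrays for Coq10b, Chac1, Ppargc1a and Slc38a2. The same held for Insc, an adaptor of spindle orientation (8.24-fold), Sik1, a salt-inducible kinase (7.61-fold), the neutral amino acid transporter Slc1a4 (6.36-fold) and the tissue-nonspecific alkaline phosphatase Alpl (6.28-fold). Sds, serine dehydratase, rose 8.63-fold, Noct, the rhythmically expressed nocturnin, 6.26-fold and Il1rn, the interleukin-1 receptor antagonist, 5.42-fold. These had 8, 9 and 9 treated arrays above every vehicle array.

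**Figure D1:**
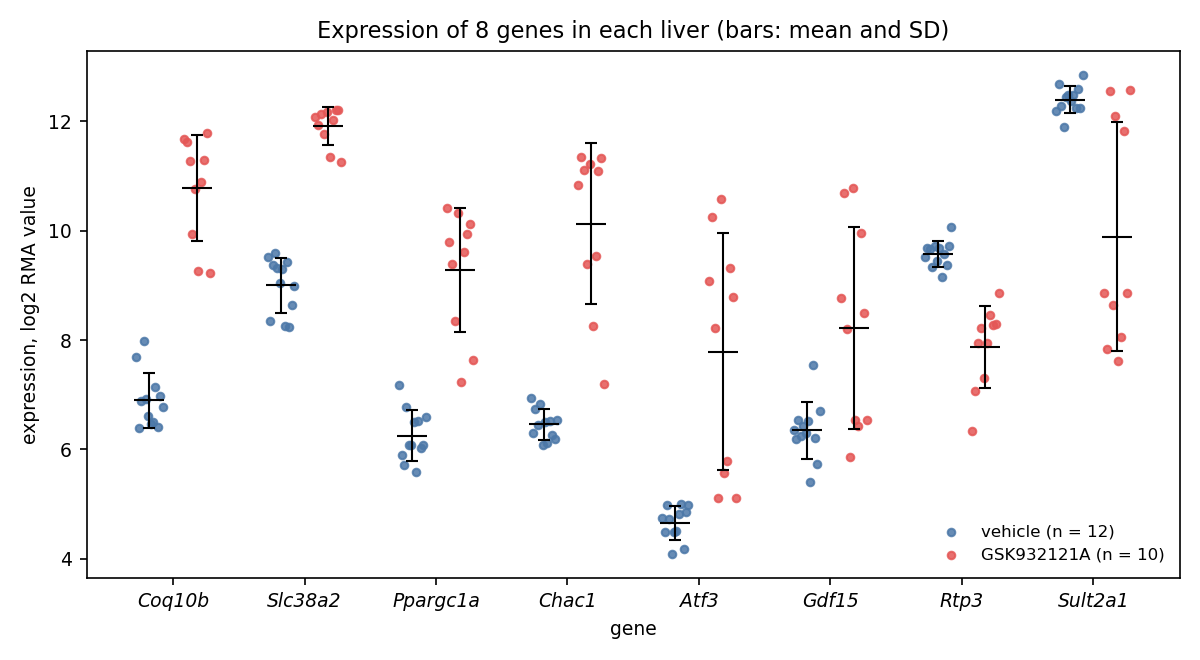
Expression of 8 genes in each liver, as log2 RMA values on the vertical axis, with 1 point per animal (12 vehicle, 10 GSK932121A) and bars for the mean and SD of each group. Coq10b, Slc38a2, Ppargc1a and Chac1 lay above every vehicle animal in all 10 treated animals, whereas Gdf15 did so in 6, and Sult2a1 lay within or close to the vehicle range in some treated animals and far below it in others.

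Among genes kept by the naming rule, which leaves out microRNAs, the largest falls were smaller than the largest rises. Sult2a2 and Sult2a1, paralogous hydroxysteroid sulfotransferases, fell 6.84-fold (adjusted p = 0.0028) and 5.67-fold (adjusted p = 0.0021), with SDs of 2.37 and 2.09 among the treated arrays against 0.41 and 0.25 among the vehicle arrays. Probes for such close paralogs can read each other's transcripts. Falls shared by all 10 treated arrays, each below the lowest vehicle array, were seen for Rtp3, a receptor-transporting protein (3.26-fold, adjusted p = 2.64e-06), Lpar6, a lysophosphatidic acid receptor (2.20-fold), Rnf186, a ubiquitin ligase (2.16-fold), Arhgap29 (2.04-fold) and Rsrp1 (2.02-fold). Osgin1, an oxidative stress-induced growth inhibitor, fell 2.90-fold, and Angptl4, an inhibitor of lipoprotein lipase, fell 2.10-fold. Cfap95 fell 4.23-fold, but its SD was 1.70 among the vehicle arrays, and only 1 treated array lay below all of them. The remaining genes of the 15 falls named by rule were Cbln3, Cyp3a73, Rbm12b, Hykk and Sertad3, which fell between 2.31-fold and 1.96-fold.

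Over all 18166 genes tested, 2244 (12.4%) passed at an adjusted p under 0.05, of which 964 rose and 1280 fell. The balance depended on the normalisation: with cyclic loess 1119 rose and 1001 fell. Large changes were mostly rises: of the 436 genes that passed and changed at least 1.5-fold, 315 rose and 121 fell, and of the 146 that changed at least 2-fold, 130 rose and 16 fell. Of the 4199 genes with a mean log2 value of 7 or more, tested alone, 1217 passed, a larger share than over all genes. Tested against a fold change of 1.2 in place of none, 313 genes passed, and 230 of them rose. With 5 surrogate variables for hidden factors, an alternative added after the data were seen, 603 passed, of which 334 rose and 269 fell. These variables accounted for 45.5% of the variance of group, so a call lost in this fit may be lost to a shared group difference. Of the 144 called genes named in the text, 65 then lost their call, among them Atf3 (adjusted p = 0.0904), Nr4a1 (0.14), Jun (0.21), Sult2a2 (0.159) and Pck1 (0.069).

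The genes of complex III, the named target, were examined next. Of 13 measured genes for complex III subunits and assembly factors, 1 passed: Uqcc3, an assembly factor, fell 1.24-fold, from 5.59 ± 0.24 to 5.28 ± 0.20 (SD, n = 12 and 10; limma, adjusted p = 0.0283). Adjusted over the list alone, 2 genes passed, the other being the core subunit Uqcrc2, with a log2 difference of -0.23 ± 0.08 (SE; adjusted p = 0.056 over all genes). Log2 differences of the 13 genes ran from -0.31 to 0.16 with a median of -0.14, and 11 of them were below 0. The subunit genes Uqcrb, Uqcrh, Uqcrq and Uqcr11 and the assembly factor Lyrm7 differed by -0.19, -0.19, -0.18, -0.16 and -0.14, Bcs1l and Uqcrc1 by -0.05 each, and the assembly factors Uqcc2 and Ttc19 by 0.16 and 0.14, none of which passed. Cyc1, which encodes cytochrome c1, differed by -0.05 ± 0.05, and Uqcrfs1, the Rieske iron-sulfur protein, by -0.03 ± 0.07. The list as a whole did not pass (camera, adjusted p = 0.279). The call of Uqcc3 was lost with surrogate variables (adjusted p = 0.439) and when any of 5 arrays was left out, with adjusted p up to 0.0597 (without GSK932121A replicate 14). No complex III gene passed without vehicle replicates 7 or 11 or without GSK932121A replicates 14 or 18, where the count was 0, and the count was 2 without vehicle replicates 2, 3, 6 or 10 or GSK932121A replicate 20.

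Few other genes of the respiratory chain passed. Among 33 complex I subunit genes, Ndufa5 rose 1.41-fold (adjusted p = 0.000147), and Ndufa6 and Ndufc1 fell 1.24-fold and 1.21-fold. In limma, 0 of 26 genes for subunits of complexes II, IV and V passed, with 2 at an unadjusted p under 0.05, 0 by the Welch test and 1 by the rank test. Of 3 mitochondrially encoded transcripts, 0 passed in limma, at an unadjusted p under 0.05 or in either other test. Neither the complex I list (camera, adjusted p = 0.155) nor that of complexes II, IV and V (0.157) passed. Among 15 regulators of mitochondrial biogenesis and mitochondrial DNA maintenance, Ppargc1a, its homologue Ppargc1b (2.61-fold) and the related coactivator Pprc1 (1.33-fold) rose. Twnk, the mitochondrial DNA helicase, fell 1.33-fold and Polg2, the accessory subunit of the mitochondrial DNA polymerase, 1.32-fold, and the list did not pass (camera, adjusted p = 0.41). Of 16 mitochondrial chaperone and protease genes, only Afg3l2 passed, at 1.14-fold, and its call was lost when any of 13 arrays was left out, with adjusted p up to 0.0809 (without GSK932121A replicate 21). Surrogate variables ended the calls of Ndufa5 (adjusted p = 0.0934), Ndufa6 (0.101), Ndufc1 (0.184), Twnk (0.104), Polg2 (0.25) and Afg3l2 (0.362).

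Gene lists fixed from textbook knowledge were then compared with all other genes. Of 43 lists with at least 5 measured members, 10 passed camera at an adjusted p under 0.05, and all 10 were shifted upwards. Camera with the preset correlation also called lists in most other groupings of the arrays, as given in the closing section. Its adjusted p, here and below, can therefore be too small. With an estimated correlation between genes in place of a preset one, 3 lists held: glucocorticoid-responsive genes, the integrated stress response and ribosome biogenesis. By fry, which tests whether a list moves one way on balance, 18 passed, 14 upwards and 4 downwards. The 4 downward lists were cytosolic chaperones (adjusted p = 0.0252), drug metabolism genes of CAR and PXR (0.0387), proteins secreted by hepatocytes (0.00802) and pericentral genes (0.00802). The upward lists that camera had not called were metallothionein and zinc genes (0.000919), pyrimidine and purine synthesis (0.0133), p53 targets (0.0149) and clock genes (0.0149). By camera on ranks 10 passed: gluconeogenesis and FoxO targets lost their call, and CAR and PXR genes (0.0404) and fatty acid oxidation (0.0364) gained one downwards.

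Glucocorticoid-responsive genes rose almost throughout. Of 16 measured members, 15 rose and none fell, and 16 rose when adjusted over the list alone (camera, adjusted p = 2.99e-25; adjusted p = 0.00139 with an estimated correlation). Gadd45g rose 6.59-fold, the metallothionein gene Mt2A 3.73-fold, Igfbp1, an insulin-like growth factor-binding protein, 3.57-fold, and Zbtb16, a zinc finger transcription factor, 3.33-fold. Per1, a clock gene with a glucocorticoid response element, rose 3.28-fold and Tat, tyrosine aminotransferase, 2.36-fold, from 11.61 ± 0.35 to 12.85 ± 0.16 (SD, n = 12 and 10). The mean of the list lay above the highest vehicle array in all 10 treated arrays.

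Targets of the integrated stress response and its transcription factor ATF4 also rose. Of 37 measured members, 15 rose and 3 fell, and 18 rose and 3 fell when adjusted over the list alone (camera, adjusted p = 5.45e-10; adjusted p = 0.00139 with an estimated correlation). Beside Chac1, Atf3, a stress-induced transcription factor, rose 8.73-fold (adjusted p = 0.000325) and Nupr1, a stress-induced chromatin protein, 2.69-fold. The vehicle mean of Atf3, 4.66, lay below every array median, so its fold is measured from near the background and may be compressed. Gdf15, a circulating stress cytokine, rose 3.67-fold (adjusted p = 0.011), but its SD was 1.84 among treated and 0.52 among vehicle arrays, and 6 of 10 treated arrays lay above every vehicle array. Its call was lost with surrogate variables (adjusted p = 0.87) and with the Wilcoxon rank sum test (adjusted p = 0.0685). Members that fell were Slc7a5, the large neutral amino acid transporter (1.59-fold), Cth, cystathionine gamma-lyase, and Eif4ebp1, a translation repressor, whose call was lost when any of 15 arrays was left out, with adjusted p up to 0.106 (without GSK932121A replicate 13). Cyclic loess normalisation ended the calls of Cth (adjusted p = 0.0738) and Eif4ebp1 (0.0767). Fgf21, a hormone released by stressed or fasted liver, differed by 0.44 ± 0.18 (SE) on the log2 scale, and this did not pass (adjusted p = 0.123). Chaperones of the endoplasmic reticulum and other unfolded protein response genes did not move as a list (camera, adjusted p = 0.712): of 22, Edem1 rose 1.59-fold and Xbp1 fell 1.32-fold, a call lost with surrogate variables (adjusted p = 0.624).

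**Figure D2:**
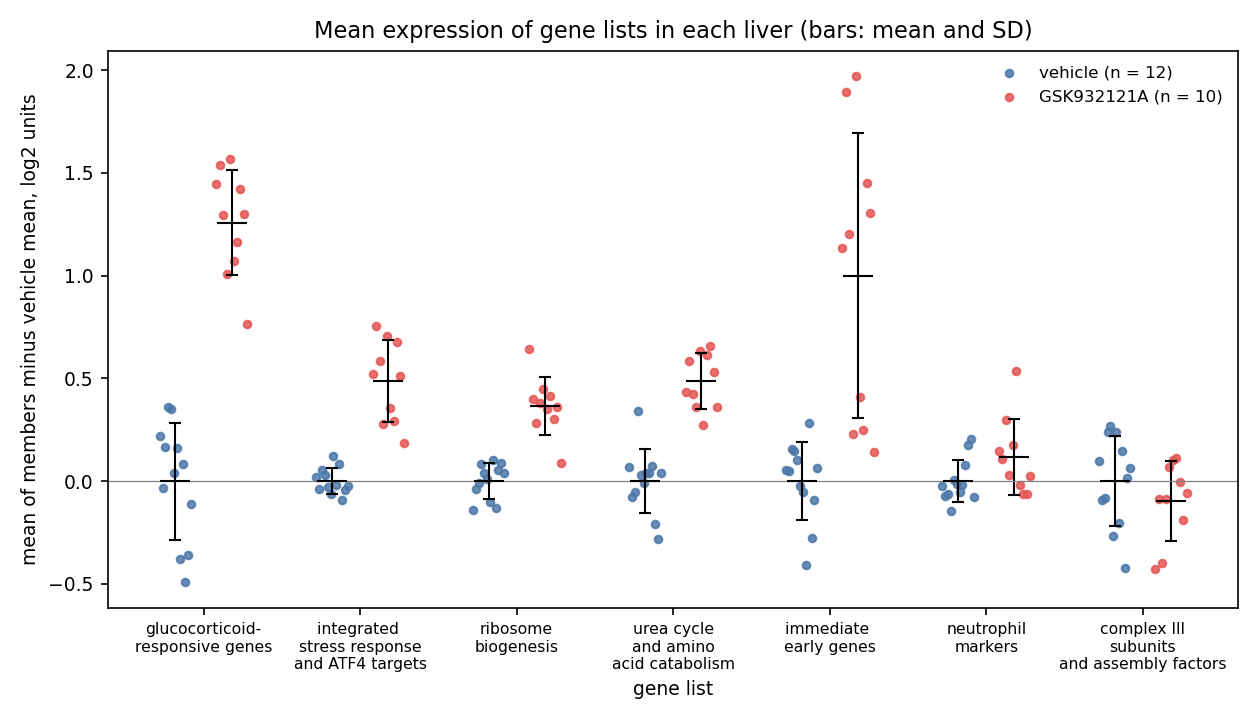
Mean log2 value of the members of 7 gene lists in each liver, relative to the vehicle mean, with 1 point per animal (12 vehicle, 10 GSK932121A) and bars for the mean and SD. All 10 treated animals lay above every vehicle animal for glucocorticoid-responsive genes and for the integrated stress response, and 7 did so for immediate early genes, which spread from 0.14 to 1.97.

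Ribosome biogenesis genes rose by smaller amounts. Of 20 measured members, 13 rose and none fell, and 17 rose when adjusted over the list alone (camera, adjusted p = 2.07e-13; adjusted p = 0.0286 with an estimated correlation). Wdr43 rose 1.75-fold, Gnl3, the nucleolar GTPase nucleostemin, 1.72-fold, Nop58, a small nucleolar ribonucleoprotein component, 1.64-fold and Ddx21, a nucleolar RNA helicase, 1.58-fold. Pyrimidine and purine synthesis genes had 3 rises among 11 members, of Ctps1, CTP synthase (1.47-fold), Ppat (1.27-fold) and Umps, by 0.26 on the log2 scale. That list did not pass camera in the main fit (adjusted p = 0.0504), but it passed camera with surrogate variables (0.021) and fry (0.0133). The call of Umps was lost when any of 15 arrays was left out, with adjusted p up to 0.0917 (without GSK932121A replicate 18).

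Immediate early genes, induced rapidly by many stimuli, rose in some treated animals far more than in others. Of 28 measured members, 14 rose and none fell, and 17 rose when adjusted over the list alone (camera, adjusted p = 1.01e-13; adjusted p = 0.138 with an estimated correlation). Nr4a1 and Nr4a3, orphan nuclear receptors, rose 5.42-fold and 5.22-fold, and Jun, a subunit of AP-1, rose 4.41-fold, from 7.19 ± 0.58 to 9.33 ± 1.47 (SD, n = 12 and 10). The vehicle means of Nr4a1 and Nr4a3, 4.62 and 4.56, lay below every array median, so their folds may be compressed. The mean of the list was 1.00 ± 0.69 in treated and 0.00 ± 0.19 in vehicle arrays (SD), and 7 of 10 treated arrays lay above the highest vehicle array.

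Genes of amino acid catabolism and gluconeogenesis rose as well. Of 24 measured genes of the urea cycle and amino acid breakdown, 12 rose and 2 fell, with the same counts adjusted over the list alone (camera, adjusted p = 5.8e-08; adjusted p = 0.114 with an estimated correlation). Beside Sds and Tat, Agxt, alanine-glyoxylate aminotransferase, rose 3.15-fold and Aass, which breaks down lysine, 2.60-fold. Nags, which makes the activator of the urea cycle, fell 1.39-fold, and Otc, ornithine transcarbamylase, fell by 0.41 on the log2 scale. Of 13 gluconeogenesis genes 6 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell (camera, adjusted p = 7.18e-05; adjusted p = 0.175 with an estimated correlation and 0.186 on ranks). Got1, cytosolic aspartate aminotransferase, rose 4.18-fold, Slc25a25, a mitochondrial carrier of ATP-Mg and phosphate, 4.01-fold and Pck1, phosphoenolpyruvate carboxykinase, 1.94-fold. The glucagon receptor gene Gcgr fell 1.32-fold, and its call was lost when any of 3 arrays was left out, with adjusted p up to 0.0605 (without GSK932121A replicate 13). It was also lost with the Welch test (adjusted p = 0.0529) and the Wilcoxon rank sum test (0.0793).

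Targets of FoxO transcription factors, which insulin represses, had 8 rises and 2 falls among 15 members, and the same counts adjusted over the list alone (camera, adjusted p = 0.000226; adjusted p = 0.251 with an estimated correlation and 0.0869 on ranks). Irs2, an insulin receptor substrate, rose 4.78-fold, Trib1, a pseudokinase, 3.76-fold and Pdk4, a kinase that shuts off pyruvate dehydrogenase, 2.22-fold. The members that fell were Ccng2, a cyclin (1.57-fold), and Sesn1, whose call was lost when any of 16 arrays was left out, with adjusted p up to 0.0871 (without GSK932121A replicate 17), and with cyclic loess (0.102). Without the members that other lists also hold, an alternative added after the data were seen, neither this list (adjusted p = 0.0675) nor gluconeogenesis (0.0696) nor the urea cycle list (0.168) passed, while fatty acid oxidation and pericentral genes then passed downwards (0.0437 each). With surrogate variables the FoxO list did not pass either (0.18).

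Acute-phase genes had 7 rises and no fall among 23 members, the same adjusted over the list alone (camera, adjusted p = 2.69e-05; adjusted p = 0.251 with an estimated correlation). Beside Il1rn, Socs3, a feedback inhibitor of cytokine signalling, rose 3.11-fold, Il1r1, an interleukin-1 receptor, 2.27-fold and Tfrc, the transferrin receptor, 1.67-fold. Inflammatory cytokines and targets of NF-kB had 7 rises and 2 falls among 25, and 9 rises and 2 falls adjusted over the list alone (camera, adjusted p = 0.00324; adjusted p = 0.296 with an estimated correlation). That list did not pass with surrogate variables (adjusted p = 0.207). Nfkbiz, an atypical inhibitor of NF-kB, rose 2.41-fold, the neutrophil chemokine Cxcl1 2.40-fold, Ccl3 1.82-fold and Nfkbia, which encodes IkB-alpha, 1.77-fold. The members that fell were Cxcl11 and Irf1 (1.53-fold), both targets of interferon, and the calls of Cxcl1 and Irf1 were lost with the Welch test (adjusted p = 0.082 and 0.0702). That of Irf1 was also lost when any of 4 arrays was left out, with adjusted p up to 0.0587 (without GSK932121A replicate 13). Surrogate variables ended the calls of Nfkbiz (adjusted p = 0.676), Cxcl1 (0.175), Ccl3 (0.0702), Irf1 (0.664), Cxcl11 (0.0563) and Tfrc (0.477).

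**Figure D3:**
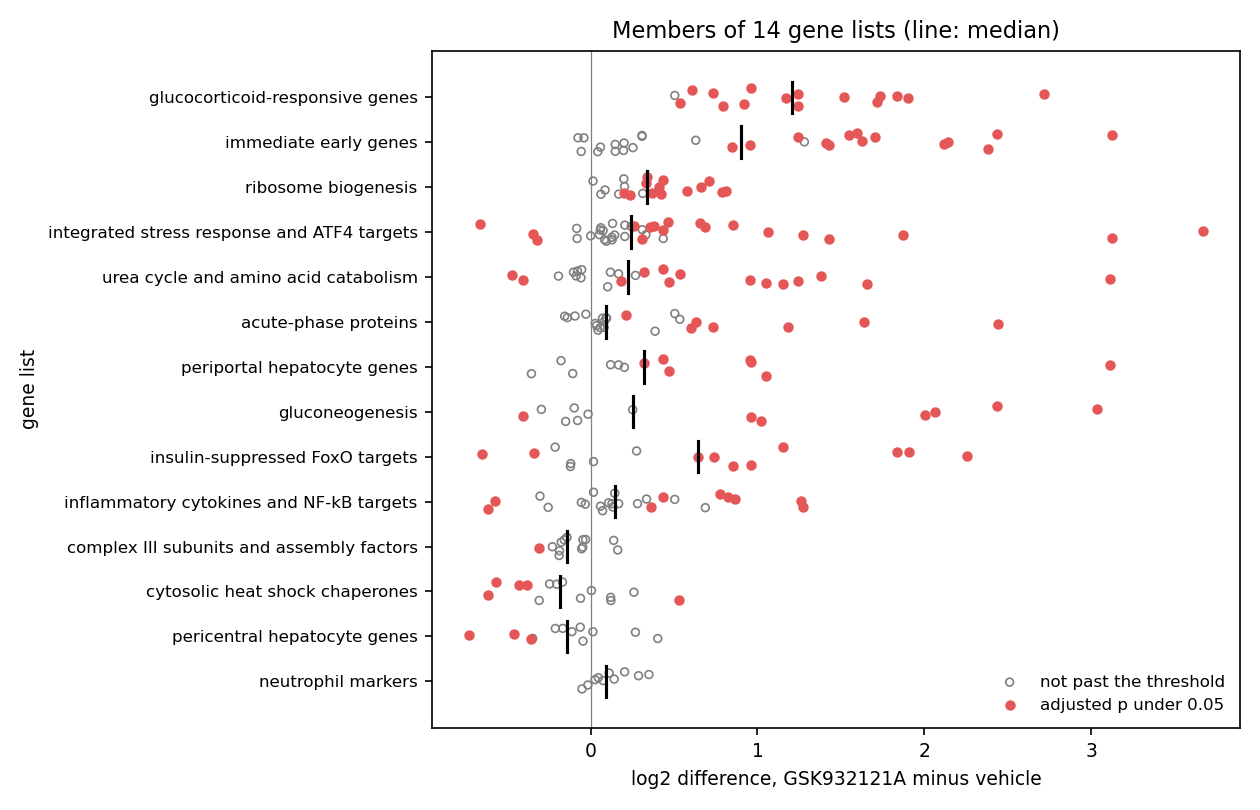
Log2 difference between GSK932121A and vehicle (horizontal axis, n = 10 and 12) for each measured member of 14 gene lists, with filled points for genes past an adjusted p of 0.05 and a line at each list's median. In the glucocorticoid list 15 of 16 points are filled and lie to the right of 0, while 1 of 13 complex III points is filled.

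Lipid and sterol genes moved both ways. Lpin1, a phosphatidate phosphatase, rose 4.65-fold (adjusted p = 4.97e-08), Pnpla3 2.07-fold and Acaca, acetyl-CoA carboxylase, 1.42-fold, while Agpat2 fell 1.36-fold and Gpam and Fads1 fell by 0.35 and 0.25 on the log2 scale. These are the called members among 18 fatty acid and triglyceride synthesis genes (camera, adjusted p = 0.213). Of 30 genes of fatty acid oxidation, ketogenesis and PPAR alpha targets, Pdk4 and Plin2, a lipid droplet coat protein (1.76-fold), rose, and Angptl4, Decr1, Creb3l3 and Acsl1 fell (camera, adjusted p = 0.0989). Of 19 cholesterol synthesis genes, Stard4, a sterol carrier, rose 2.43-fold, Insig1, which retains the sterol sensor in the endoplasmic reticulum, 2.15-fold and Pmvk 1.36-fold. That list had a median of -0.04, a mean of 0.17 and an upward test that did not pass (camera, adjusted p = 0.213). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 1.44-fold, and Baat and the bile acid uptake transporter Slco1b2 fell by 0.37 and 0.33 on the log2 scale, among 15 bile acid genes (camera, adjusted p = 0.286). The calls of Cyp7a1 and Pmvk were lost with surrogate variables (adjusted p = 0.355 and 0.776) and with the Wilcoxon rank sum test (0.0924 and 0.0793). The latter test also ended the call of Acaca (adjusted p = 0.0584). On leaving out 1 array, the call of Gpam was lost for 14 arrays (adjusted p up to 0.0968 without GSK932121A replicate 13), that of Decr1 for 13 (up to 0.0831 without GSK932121A replicate 21) and that of Acsl1 for 1 (0.0548, without GSK932121A replicate 18). The call of Acsl1 was also lost after renewed quantile normalisation (adjusted p = 0.111), cyclic loess (0.178) and with surrogate variables (0.245). Cyclic loess ended those of Fads1 (0.0883), Decr1 (0.0853) and Gpam (0.115) as well.

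Among 14 p53 targets, 4 rose and 3 fell: Tp53inp1 rose 3.29-fold, Cdkn1a, the cell cycle inhibitor p21, 2.87-fold, Gadd45a 2.73-fold and Aen 1.63-fold, while the death receptor Fas fell 1.42-fold and Phlda3 and Sesn1 fell by 0.42 and 0.34 on the log2 scale (camera, adjusted p = 0.223). Of 24 NRF2 targets, Hmox1, heme oxygenase 1, rose 2.22-fold and Gclm fell 1.32-fold beside Osgin1 (adjusted p = 0.286). Of 24 targets of hypoxia-inducible factor, Bhlhe40 rose 2.35-fold, Cited2 1.67-fold and Pfkfb3 1.44-fold, and Mxi1 and P4ha1 fell (adjusted p = 0.213). The calls of Cited2 and Pfkfb3 were lost with the Welch test (adjusted p = 0.113 and 0.0569), and with surrogate variables Cited2 differed by -0.17, in the other direction. Aldolase A, Aldoa, was the called gene among 12 of glycolysis, at 1.27-fold (adjusted p = 0.27 for the list). The call of Phlda3 was lost when either of 2 arrays was left out, with adjusted p up to 0.0567 (without GSK932121A replicate 13).

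Among 14 cytosolic chaperone genes, 4 fell and 1 rose. Hspa8, the constitutive heat shock cognate protein, fell 1.53-fold, with all 10 treated arrays below the lowest vehicle array, and Chordc1, Dnaja1 and Dnajb1 fell by 0.57, 0.43 and 0.38 on the log2 scale, while Hspb8 rose 1.44-fold (camera, adjusted p = 0.092), a call lost with the Welch test (adjusted p = 0.0533). The labels state that the animals carried microchips for body temperature, whose readings were not used here. Among 3 genes listed as cold-inducible, too few for camera, Rbm3, which encodes an RNA-binding protein, rose 1.73-fold, with all 10 treated arrays above every vehicle array (adjusted p = 5.77e-06), and Cirbp rose 1.24-fold (adjusted p = 0.037). The call of Cirbp was lost when any of 12 arrays was left out, with adjusted p up to 0.079 (without GSK932121A replicate 18). It was also lost with the Welch test (adjusted p = 0.0932) and the Wilcoxon rank sum test (0.0924). Of 5 metallothionein and zinc genes, Mt2A, Mt1 (3.14-fold) and Slc39a14 (1.59-fold) rose and Slc30a1, a zinc exporter, and Slc30a10, a manganese exporter, fell (adjusted p = 0.12), the latter short of a call with cyclic loess (0.0501).

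Among 17 clock genes, Nfil3 rose 2.49-fold and Rora 1.90-fold beside Per1, Bhlhe40 and Usp2, and Per2 fell 1.29-fold (camera, adjusted p = 0.0604). The call of Usp2 was lost when any of 11 arrays was left out (adjusted p up to 0.0669 without GSK932121A replicate 22), and that of Per2 when any of 7 was (up to 0.0656 without GSK932121A replicate 13). Of 17 drug metabolism genes of the receptors CAR and PXR, Por, cytochrome P450 reductase, rose 2.18-fold and Nr1i2, which encodes PXR, 1.47-fold, and Cyp3a18, Akr1b7 and Nr1i3, which encodes CAR, fell (adjusted p = 0.155). The call of Akr1b7 was lost when any of 9 arrays was left out, with adjusted p up to 0.0644 (without GSK932121A replicate 13), and with cyclic loess (0.0615). Of 5 targets of the aryl hydrocarbon receptor, 0 passed in limma, at an unadjusted p under 0.05, or by the Welch or rank test (camera, adjusted p = 0.412). Autophagy and lysosome genes (19 measured) had 1 rise, of Uvrag, and 1 fall, of Atg9a, and cell cycle genes (21 measured) had 1 rise, of Mcm4. Neither list passed (adjusted p = 0.841 and 0.34), and the call of Mcm4 was lost when either of 2 arrays was left out, with adjusted p up to 0.0521 (without GSK932121A replicate 13).

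Markers of hepatocyte zones and of other liver cells were compared next. Genes of periportal hepatocytes had 7 rises and no fall among 13, and 8 rises and 2 falls adjusted over the list alone (camera, adjusted p = 2.69e-05; adjusted p = 0.0813 with an estimated correlation). Asl, argininosuccinate lyase, rose 2.07-fold and Arg1, arginase, 1.94-fold, beside Sds and Pck1, and 8 of the 13 members stand in another list too. The direction of the list turned downwards on the other 5 members (adjusted p = 0.398). Genes of pericentral hepatocytes had 3 falls and no rise among 12: Tbx3 fell 1.66-fold, Axin2, a target of Wnt signalling, 1.37-fold and Rnf43 1.28-fold (adjusted p = 0.0781, and 0.0158 with surrogate variables). The call of Rnf43 was lost when any of 9 arrays was left out, with adjusted p up to 0.0753 (without GSK932121A replicate 13). Although the list passed with surrogate variables, the calls of Tbx3, Axin2 and Rnf43 were all lost with them (adjusted p = 0.0582, 0.217 and 0.134). Of 12 proteins secreted by hepatocytes, Apoh fell 1.15-fold (adjusted p = 0.149 for the list), and Alb, albumin, differed by -0.03 ± 0.04 (SE).

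None of the lists for cells other than hepatocytes passed. Kupffer cell and macrophage markers (camera, adjusted p = 0.288) had 1 rise among 13, of the scavenger receptor Cd163 (1.28-fold). Sinusoidal endothelial markers (adjusted p = 0.155) had 1 among 9, of Lyve1 (1.16-fold), and cholangiocyte markers (adjusted p = 0.213) had 1 among 8, of Cldn4 (1.24-fold). In limma 0 of 10 neutrophil markers passed (camera, adjusted p = 0.173), and so did 0 of 12 stellate cell and fibroblast markers (0.572), 0 of 15 lymphocyte markers (0.66), 0 of 6 blood cell markers (0.66), 0 of 12 mesothelial and pancreatic markers (0.931) and 0 of 8 adipocyte markers (0.669). At an unadjusted p under 0.05 these counts were 0, 2, 5, 0, 1 and 2, and by the Welch test and by the rank test they were 0 in each of these lists. The calls of Cd163, Lyve1 and Cldn4 were lost with surrogate variables (adjusted p = 0.2, 0.0922 and 0.0921), with which the cholangiocyte list passed (0.0425). Single animals stood apart: the mean of the cholangiocyte list was 0.54 and 0.57 in GSK932121A replicates 18 and 24 (highest vehicle array 0.26). That of the stellate cell and fibroblast list was 0.43 and 0.41 in them (highest vehicle array 0.16).

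The last comparison asked how far the arrays separate by group and whether treated animals vary more. The first principal component over all genes held 24.9% of the variance, and its score was 17.7 ± 11.6 in treated and -14.8 ± 1.79 in vehicle arrays (SD, n = 10 and 12), a difference of 32.5 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). All treated arrays lay above the highest vehicle array at -10.8, from -2.56 for GSK932121A replicate 24 to 30.5 for replicate 14. Over all genes, the median log2 ratio of the SD among treated arrays to that among vehicle arrays was 0.011, and a difference from 0 was not detected (two-sided permutation test, p = 0.833). The median of this ratio was 0.93 for immediate early genes and -0.64 for glucocorticoid-responsive genes, neither of which was tested by permutation.

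**Figure D4:**
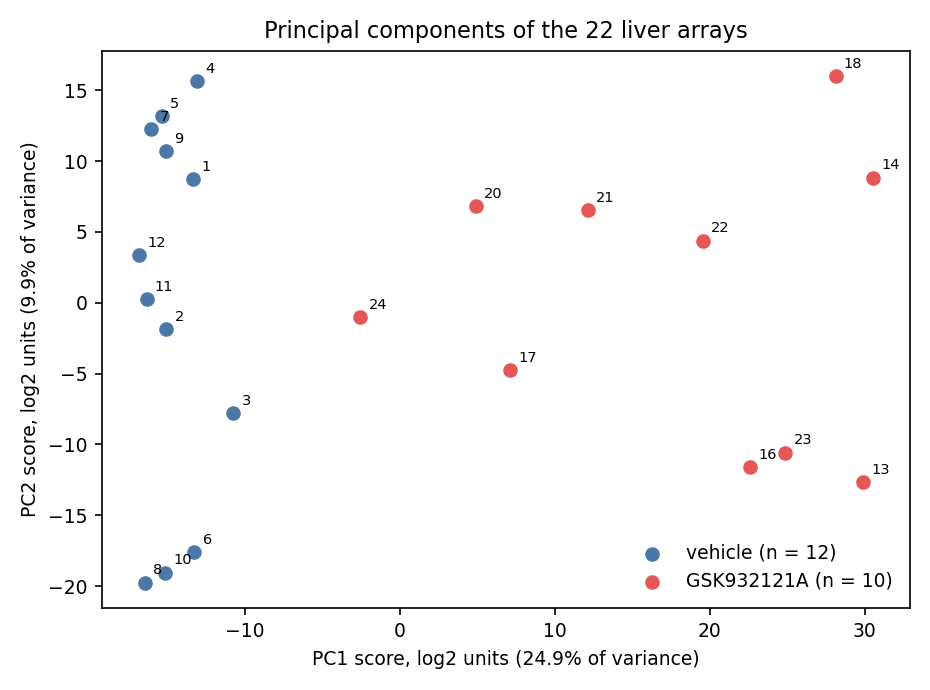
Scores of the 22 arrays on the first principal component (horizontal axis, 24.9% of the variance) and the second (vertical axis, 9.9%), in log2 units, with 1 point per animal labelled with its replicate number. The 12 vehicle arrays lie between -16.9 and -10.8 on the first component and the 10 treated arrays between -2.56 and 30.5.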

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

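The tests in this part were chosen after the results were seen, except the planned search for far arrays in the treated group, fit over all probe sets, spread over all genes (also on leaving out 1 array), camera with preset or estimated correlation, and fry.

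The 2244 genes that passed exceeded what other groupings of the arrays gave: of 100 splits into 12 and 10 arrays, the real one included, 1 gave as many. The highest of the others gave 747, but that split has 1 treated array in its group of 10, so it nearly reverses the real split. Of the 51 others with 4 or 5 treated arrays in the group of 10, 0 passed any gene. Chance is therefore argued against, but 1 of 100 is the smallest count possible here, so it is not excluded. For complex III, 1 of 100 splits gave as many as the 1 gene that passed, and the highest of the others gave 0, but only 3 of the 99 others passed any gene at all, which fixed their count at 0 in advance. These splits therefore decide nothing about complex III. For the number of gene lists, 20 of 100 splits gave at least the real 10, and the highest of the others gave 16. If the groups did not differ, all 100 splits would be alike, so by this count the number of lists does not stand out from chance. If the groups differ, splits that place the treated arrays unevenly keep part of that difference. Of the others, 17 of 48 such splits reached 10 lists. Of the 51 with 4 or 5 treated arrays in the group of 10, 2 did, and the highest was 13. These 51 passed 0 genes, yet in most of them camera with the preset correlation called at least 1 list. Its adjusted p can therefore be too small, and a call by it alone is weak evidence for a list. With the real split added to these 51, 3 of 52 (5.8%) gave at least 10. These 51 were chosen for an evenness that the real split lacks, so this share is no test. Chance cannot be excluded for the number of lists. List by list, the number of splits with a p as small, the real one included, was 1 for glucocorticoid-responsive genes, the integrated stress response, immediate early genes, gluconeogenesis, the urea cycle and periportal genes. It was 2 for acute-phase genes, 3 for FoxO targets and for ribosome biogenesis, and 11 for inflammatory genes. If the groups differ, the uneven splits can raise these counts. If they did not differ, all splits would be alike, so 11 of 100 does not set the inflammatory list apart from chance. A count of 1 is the smallest possible here, and the counts were not adjusted over the lists.

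In 17 of the 205 results searched (8.3%), 1 treated array lay far from the other treated arrays, with a gap that exceeded Dixon's 95% critical value as a share of the group's range, which chance alone gives in about 1 in 20 groups. Of these, 5 were at GSK932121A replicate 24: low Mt2A (gap over range 0.721), Mt1 (0.603), Il1r1 (0.524) and metallothionein list (0.667), and a high adipocyte list (0.505). Replicate 13 was low for Ndufc1 (0.501), Eif4ebp1 (0.635) and Otc (0.685). Replicate 18 was high for Cfap95 (0.82) and Cyp3a18 (0.604) and low for Slc30a1 (0.506). Replicate 20 was low for Arg1 (0.507) and Cth (0.58), replicate 14 for Alb (0.538) and replicate 22 for the mitochondrially encoded transcripts (0.551). Replicate 21 was high for Aldoa (0.673) and replicate 16 for the cell cycle list (0.651). The vehicle group, with 12 arrays, was not searched.

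Probe sets without a single gene name also changed: in the fit over all probe sets, 781 of 18174 passed, of which 360 were higher and 421 lower after GSK932121A. At least 2-fold changes numbered 102, of which 61 were higher and 41 lower, with log2 differences from -2.40 to 4.02.

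Immediate early genes varied more between treated than between vehicle animals, with a median SD ratio of 1.91 over 28 members. The spread was not particular to this list. Replicates 17, 20, 21 and 24 had 0.14 to 0.41 for immediate early genes, against 1.14 to 1.97 in the other treated animals. They were also lowest for the integrated stress response (0.18 to 0.36 against 0.51 to 0.76). The same held for FoxO targets (0.18 to 0.39 against 0.68 to 1.12) and the first principal component (-2.56 to 12.1 against 19.5 to 30.5). Noisier arrays in the treated group are argued against by the median log2 SD ratio of all genes, 0.0106 (-0.0178 to 0.034 leaving out 1 array), against 0.93 for the list. Compression of low signals stays open. The list lay at percentile 99.4 among 10000 random lists matched on vehicle level and log2 difference, whose median was 0.36, but it was picked for this ratio, and its members move together. Over resampled arrays its 95% bootstrap interval was 0.52 to 1.5, which includes 0.81, the upper end of the central 95% of the random lists. Leukocytes in some livers stay open too: the median log2 SD ratio of 38 leukocyte markers was -0.14 (95% bootstrap interval -0.44 to 0.01). That interval came from resampled markers, not animals, so it leaves out the spread between animals. The highest vehicle mean of a neutrophil marker was also only 4.83, near the array median. The mean of the neutrophil list had an SD of 0.19 among treated and 0.10 among vehicle arrays, but it did not follow the immediate early list: its highest value, 0.54, was in replicate 20, with 0.41 for immediate early genes. Replicates 18, 14 and 22, the highest for immediate early genes (1.97, 1.89 and 1.45), had 0.17, 0.11 and -0.06. Differences in exposure between animals may contribute, which was not tested.

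Sult2a1 took widely separated values among the treated animals: 7.62, 7.83, 8.05, 8.64, 8.86 and 8.86 in replicates 20, 14, 21, 17, 13 and 23, and 11.82, 12.10, 12.55 and 12.58 in replicates 22, 18, 16 and 24, against 11.89 to 12.85 in vehicle animals. Livers of male animals are argued against by Cyp2c12, a transcript of female rat liver, whose lowest treated value was 12.7 (vehicle 12.74 to 12.98). An inherited difference between animals and an effect of the compound cannot be told apart: values more than 1 log2 unit below the lowest vehicle array occurred in 6 of 10 treated and 0 of 12 vehicle animals (Fisher's exact test, two-sided, p = 0.00281), but the gene was picked for this pattern. Gaps of at least 2 log2 units with 2 or more arrays on each side were seen for 9 genes among treated and 8 among vehicle arrays, 4 of them shared. Probes for Sult2a2 may read the same transcript, so it is no independent case.

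Periportal genes rose as a list (camera, adjusted p = 2.69e-05), a call lost with an estimated correlation (0.0813). A larger share of periportal tissue in the treated pieces as the whole cause is argued against by the 5 members that no other list holds: Cyp2f4 (-0.35), Hsd17b13 (-0.18), Pigr (-0.11), Hsd17b6 (0.12) and Aldh1b1 (0.20), none of which passed. Their mean log2 difference was -0.06 (95% bootstrap interval -0.16 to 0.03) against a median of 0.32 for the whole list and 0.71 for the 8 shared members. Adjusted over the list alone, Cyp2f4 and Hsd17b13 passed as falls. Pericentral genes, with 3 falls and no rise, or 4 falls and 1 rise adjusted over the list alone, go in part with a larger periportal share (adjusted p = 0.0781 by camera, 0.0437 without shared members, 0.0158 with surrogate variables, 0.296 with an estimated correlation and 0.00802 by fry), so a partial contribution of tissue share stays open. Induction of the shared genes in hepatocytes stays open too and was not tested.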

How the results depend on the processing

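All alternatives given here were planned except the lists without shared members and limma's surrogate variables, which were added after the data were seen. The planned surrogate variables of the sva package were not run for the values given here. Of 144 called genes named in the text, 73 kept their call in every one of 11 settings and in each of 22 fits without 1 array, where a value was had, and 127 kept it in all fits without 1 array. Most losses came with surrogate variables (65), the Wilcoxon rank sum test (20) and the Welch test (18). The called gene that changed direction was Cited2 (-0.1718 with surrogate variables).

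With only the 4199 genes of mean log2 value 7 or more, 1217 passed (491 higher, 726 lower), 235 of them at least 1.5-fold. These counts are lower since fewer genes were tested. Surrogate variables left 603 genes (334 higher, 269 lower), 215 at least 1.5-fold and 61 at least 2-fold. These variables accounted for 45.5% of the variance of group, so the fit shares part of the group difference with them. All probe sets gave 784 at least 1.5-fold and 251 at least 2-fold, since more features were tested. Against a 1.2-fold change 313 passed (230 higher, 83 lower), a stricter test by construction. Complex III gave 2 genes after renewed quantile normalisation, at a mean of at least 5, with the intensity trend and with the rank sum test, 0 with surrogate variables, and 0 to 2 without 1 array. An estimated correlation left 3 lists, camera on ranks gave 10, of which 2 were lower, and fry gave 18, of which 4 were lower. Without 1 array, 1854 to 2386 genes and 10 to 13 lists passed. Lists short of a call with all arrays then had lowest adjusted p of 0.0187 (fatty acid oxidation), 0.0221 (pyrimidine and purine synthesis), 0.0243 (cytosolic chaperones), 0.0293 (clock) and 0.0493 (pericentral). The share of calls that were higher was 43% and, with cyclic loess, 52.8%.

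Further turns of direction were of values that had not passed, apart from the periportal list. With cyclic loess, Uqcrfs1 was 0.0066 and Alb 0.0304. With surrogate variables Uqcrb was 0.0288, Uqcrh 0.0272, Uqcr11 0.1227, Lyrm7 0.0105 and Uqcrfs1 0.0277, and the lists of complex III (adjusted p = 0.968), complexes II, IV and V (0.903), cholesterol synthesis (0.327), Kupffer cells (0.968) and lymphocytes (0.738) turned. So did autophagy with fry (0.976), periportal genes without shared members (0.398) and the spread by median absolute deviation (-0.0031). Without 1 array, turns occurred within -0.0774 to 0.0075 for Uqcrc1, -0.0513 to 0.0015 for Uqcrfs1 and -0.0178 to 0.034 for the spread. The same held within adjusted p of 0.713 to 0.987 for mesothelial, 0.214 to 0.993 for endoplasmic reticulum stress, 0.591 to 0.993 for autophagy and 0.534 to 0.889 for adipocyte lists. Except where the construction is named, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. Signal over background was not given, so the limit it sets is unknown.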

Other observations

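All tests in this part were chosen after the results were seen, and the families of genes with a shared name were picked after falls among them were seen.

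Genes whose symbols begin with Zfp, most of which encode zinc finger proteins, were lower as a family. Of 242 measured, 51 fell (21.1%, against 6.9% of other genes) and 11 rose, with a median log2 difference of -0.111, and -0.097, -0.103 and -0.093 after median centring, renewed quantile normalisation and cyclic loess. The other genes include many dim ones. In a separate fit of the 10410 genes with a mean of at least 5, adjusted over these alone, 1422 fell, against 1280 in the fit of all genes. That count rests on another adjustment than the 6.9%. The median log2 difference was -0.034 for these brighter genes and -0.0088 for all genes. No family was compared with genes of matched level, so part of this contrast may reflect level. Relative to all genes, the family mean differed by -0.093 between groups (SD 0.071 among treated and 0.026 among vehicle arrays), and 7 of 10 treated arrays lay below the lowest vehicle array. A two-sided permutation test gave p = 0.00019 (adjusted p = 0.00057 over 3 families). It cannot decide about chance differences between animals, since the family was picked after its falls were seen, so this is a hypothesis.

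Genes for mitochondrial ribosomal proteins had 8 falls (11.1%, against 7.0% of other genes) and 1 rise among 72, with a median of -0.096, and did not pass (adjusted p = 0.076). MicroRNA precursor genes had 16 falls (4.5%, a smaller share than the 7.1% of other genes) and 5 rises among 352, with a median of -0.002 that turned to 0.012 after median centring, and did not pass as a family (adjusted p = 0.26). Single precursors changed more. Mir505 fell 4.25-fold, Mir802 3.20-fold and Mir122 1.86-fold (limma, adjusted p = 3.06e-06, 1.01e-06 and 0.0244). The largest of the rises was that of Mir1949, at 2.27-fold (0.000829). These precursors are not among the 144 called genes followed through the other settings.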
